A study of Mus musculus with 2 samples.

How the data were processed

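DNase-seq peaks and hotspots of mouse adipocytes, differentiated in vitro from 3T3-L1 cells for 8 days, were taken as deposited for 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. Per the labels, the assembly was mm10, each library combined more than 1 technical replicate, and both cultures had the same donor record. Nothing in the labels said whether the cultures were differentiated on separate days. The strain label named C57BL/6J, while 3T3-L1 is generally described as derived from Swiss mice, so no strain was assumed.

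The authors called peaks and hotspots in each library separately and did not pool replicates, as the text lists deposited with each library name 1 alignment file behind each region list. The peak caller, its version, its filters, the aligner and the sequencing depth are not given in the sources used here. The deposited peak lists hold a signal value per peak, in the seventh column of the narrowPeak layout, with whole values from 1 to 150 on peaks of 150 bp. How the authors scaled that signal is not given in the sources used here, and since the values saturate and differ in level between the libraries they served only to rank peaks within a list. The deposited hotspot lists hold the −log10 of a q value per hotspot in the layout of the broadPeak format, up to a ceiling of 100, which 46.7% and 48.5% of the hotspots reached. Identical duplicate lines (20 and 33 among the peaks) were counted once. Regions on the mitochondrial genome and on unplaced scaffolds were counted and left out of the comparisons. Signal tracks and alignments were not used here, and the depth behind each value is therefore unknown.

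Coordinates were used with the GRCm38 reference and GENCODE release M21, and all 21 chromosomes were long enough to hold every region. Positions are given counted from 1. A shared peak was a merged interval, with an overlap of at least 1 bp, that held a peak of both replicates. Chance overlap came from 100 random placements of the peaks within each chromosome, and intervals of shares are exact binomial 95% intervals over peaks. A peak was a promoter peak when its centre lay within 1000 bp of a start site of a protein-coding gene, and otherwise exonic, intronic or intergenic in that order. A gene had an accessible promoter when a peak of each replicate overlapped within 1000 bp of one of its start sites. Distal shared peaks, with centres more than 1000 bp from every such site, were assigned to the nearest one within 100 kb.

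Gene lists, motifs, the main tests and their alternatives were fixed before the data were examined, apart from those of the dense clusters and of motifs in peaks found in 1 replicate. There were 16 lists of 312 entries, of which 311 were annotated (Hbb-b1 was not), and olfactory receptor genes were added by symbol. The lists covered adipogenic transcription factors, lipid storage and lipolysis, fatty acid and triglyceride synthesis, adipokines and the insulin response, thermogenic genes, preadipocyte and fibroblast genes, glucocorticoid response and housekeeping. Others covered hepatocytes, skeletal muscle, neurons, blood and immune cells, endothelium, epithelium, pluripotent cells, and bone and cartilage. Promoter peaks and clusters were tested with two-sided Fisher's exact tests of members against all other protein-coding genes. Distal peaks were tested on the mean of log2(count + 1) with 100000 random lists matched on the decile of the territory, the length of genome that would be assigned to a gene. Each family of 17 tests was adjusted by the Benjamini-Hochberg method at 0.05. These tests treat genes as independent and describe these libraries, with no replicate error between groups.

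Motifs were 22 consensus sequences searched on either strand of the central 150 bp of distal shared peaks and of windows 1000 bp to each side that touched no peak or hotspot. The median log2 ratio of 20 column shuffles of each consensus was subtracted, and a motif was called when its ratio exceeded that of every shuffle. Clusters joined shared peaks less than 10 kb apart, and the 500 with the most peaks were tested. The name dense cluster, for at least 20 shared peaks and at least 10 per 10 kb, was defined after the clusters had been seen. Named genes followed a rule: 13 markers always, the 3 members of each list with the most distal peaks and the first 2 without a promoter peak in both replicates. To these came the 10 genes with the most distal peaks, the genes at the 10 largest clusters, and the first 5 list members with a promoter peak in 1 replicate. Some of the genes this rule gives are not reported here.

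The procedures were tested on simulated data. Simulated lists were called at an unadjusted p under 0.05, and for distal peaks with fewer draws, so their rates are not those of the adjusted tests below. For the distal peaks of gene lists, 500 simulated lists of 20 among 20000 genes were called in 5% of cases with no difference. The rate was 43% at a ratio of mean counts of 1.5 and 89.8% at a ratio of 2. For the promoter peaks of gene lists, with 20000 simulated genes, lists were called in 3.4% of cases at the background share of 55%, 95.4% at a share of 90% and 76.6% at 25%. In 10000 simulated peaks with 60% shared, the overlap returned 60%, and all 3986 C/EBP sites planted in 20000 windows for the motif search were found.

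Alternatives included reciprocal overlap of 50%, the strongest 50% of peaks, lists of equal length, hotspots in place of peaks, promoter windows of 500 and 2500 bp, and assignment within 50 and 20 kb. Others were matching on promoter CpG content or promoter state, flanks at 5000 bp, joining at 5 and 20 kb, 200 and 1000 clusters, and each replicate alone. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.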

Results

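DNase I, an endonuclease that cuts DNA where chromatin is open, was used to map accessible chromatin in mouse adipocytes. The cells had been differentiated in culture from 3T3-L1, a fibroblast-like preadipocyte line that fills with lipid droplets after hormonal induction, and were taken at day 8. The labels gave 2 biological replicates of this 1 group, and no undifferentiated or other control library was analysed here, so accessibility was described within these adipocytes and was not compared between groups. Replicate 1 held 133695 peaks on the assembled chromosomes and replicate 2 held 216556, a mean of 175126 ± 58592 (SD, n = 2). Hotspots, the broader regions of raised cutting that contain the peaks, numbered 117685 in replicate 1 and 185029 in replicate 2 and covered 45.4 and 76.4 Mb. The sequencing depth of the libraries was unknown, so no precision could be attached to a single peak, and the binomial intervals given for shares of peaks cover counting error only. The accessible regions were compared between the replicates and then with genes, gene lists and sequence motifs.

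Genes of the mature adipocyte carried accessible promoters and runs of further accessible sites. At Pparg, the nuclear receptor that directs adipocyte differentiation, 26 peaks shared by both replicates lay nearest to this gene and more than 1000 bp from the start of any protein-coding gene (31 in replicate 1 and 58 in replicate 2). The Pparg peak with the highest replicate 1 value, on chromosome 6 from 115421836 to 115422025 in GRCm38, lay at -135 bp from an internal start site of the gene. Its values were 122 in replicate 1 and 145 in replicate 2, at the percentiles 98.6 and 98.8 of the lists. Adipoq, which encodes the hormone adiponectin, had a promoter peak on chromosome 16 from 23146356 to 23146525 with values of 125 and 147, and 13 distal shared peaks. Its upstream intergenic peak from 23144476 to 23144645, with values of 111 and 142, held the C/EBP site TTGCACAA on the minus strand from 23144608 to 23144615. Fabp4, a fatty acid carrier of the adipocyte, had its strongest peak in the intergenic sequence past its 3' end on chromosome 3 from 10203076 to 10203265 (values 121 and 148). It also had a promoter peak from 10208496 to 10208705 (119 and 143) and 13 distal shared peaks.

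The other marker genes chosen in advance differed from one another. Cebpa, a transcription factor of terminal adipocyte differentiation, had a promoter peak and 10 distal shared peaks, the strongest past the end of the gene, in an intron of another gene on chromosome 7 from 35138596 to 35138745, at 19.4 kb from the start site (values 103 and 140). Plin1, the coat protein of lipid droplets, had 11 distal shared peaks, with the strongest at chromosome 7 from 79734696 to 79734865 (120 and 144), and Slc2a4, the insulin-responsive glucose transporter, had promoter peaks and 2 distal shared peaks. Lep, the gene of leptin, had 15 distal shared peaks, including an intergenic peak at -28.8 kb from the start site on chromosome 6 from 29031336 to 29031505 (116 and 145), while its promoter had a peak in replicate 2 alone. Ucp1, the uncoupling protein of brown fat, and Dlk1, a preadipocyte gene that represses differentiation, had no promoter peak in either replicate, with 5 and 6 distal shared peaks. The Ucp1 peak with the highest replicate 1 value, in an intron of a neighbouring gene on chromosome 8 from 83260556 to 83260725, stood at the percentile 54.1 of the replicate 1 list and 78.3 of the replicate 2 list. Markers of other lineages, namely Alb of hepatocytes, Ptprc of blood cells, Myod1 of muscle and Nanog of pluripotent cells, likewise had no promoter peak, with 2, 4, 1 and 6 distal shared peaks. Distal counts expected from territory length were 0.544 at Slc2a4, 3.125 at Ucp1, 5.117 at Dlk1 and 4.778 at Ptprc. They were 2.284 each at Alb, Myod1 and Nanog, so the raw counts do not rank these genes. Peak values are the authors' own and saturate near 150, and they were used only to rank peaks within a list.

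**Figure D1:**
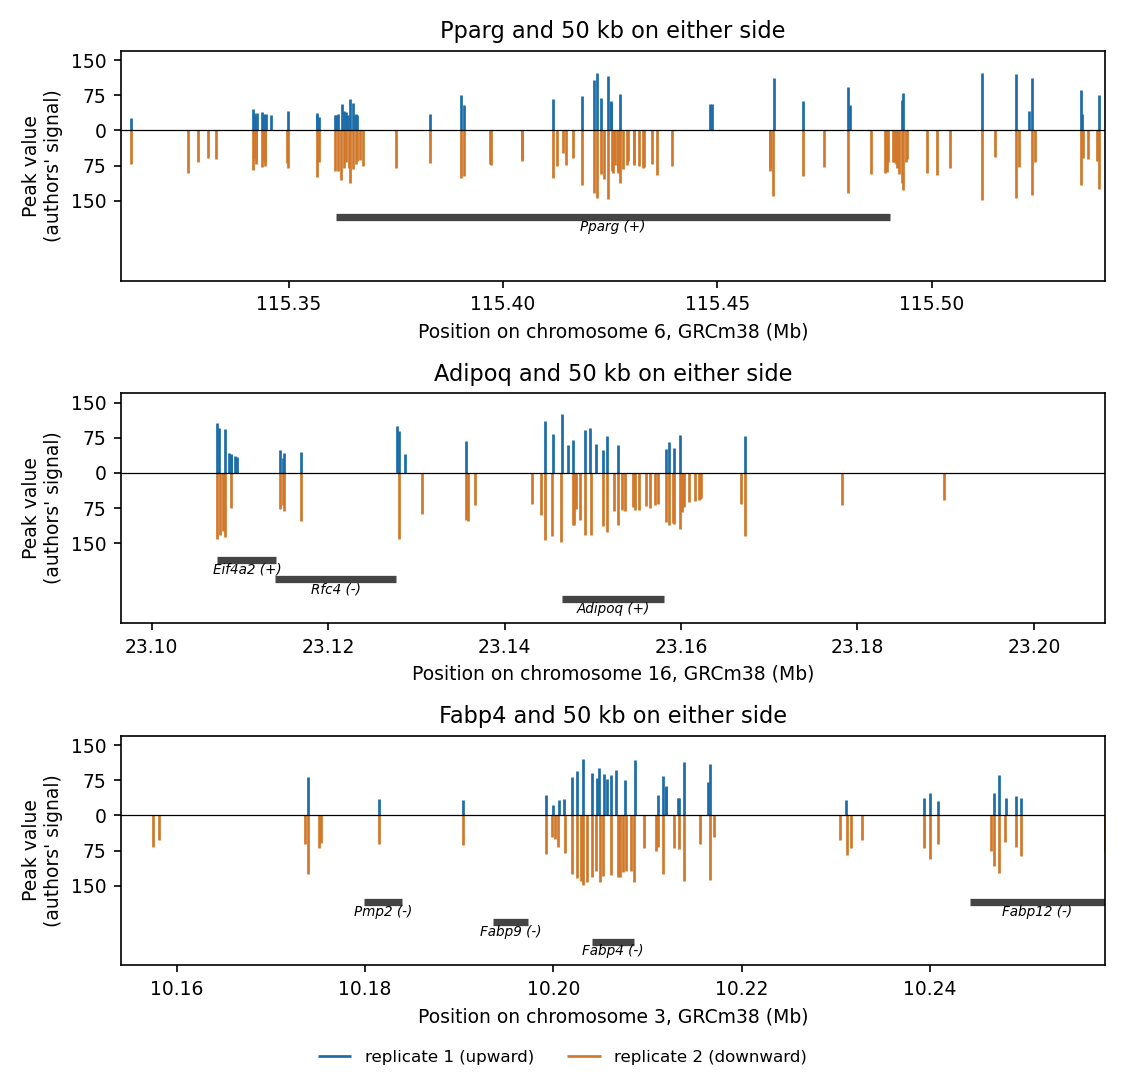
Peaks around Pparg, Adipoq and Fabp4 with 50 kb on either side, by position in Mb (horizontal axis) and authors' peak value (vertical axis), with replicate 1 drawn upward, replicate 2 downward, and protein-coding genes as grey bars with their strand. Strong peaks stand at the same places in both replicates, and replicate 2 has more of the weaker ones, with 98 peaks against 53 in the Pparg window.

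Nearly every accessible site of replicate 1 was found again in replicate 2, whereas many sites of replicate 2 had no partner. Of the replicate 1 peaks, 90.3% (exact 95% interval 90.1 to 90.4) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 55.5% (55.3 to 55.7) overlapped a replicate 1 peak. Random placement of the same peaks on each chromosome gave a mean overlap of 2.56% and 1.59%. Sharing rose with peak strength: among the strongest 10% of replicate 2 peaks 96.6% had a partner and among the weakest 10% the figure was 11.5%. Merged across the lists, 117590 regions held a peak of both replicates, 12194 a peak of replicate 1 alone and 91754 a peak of replicate 2 alone. Across the shared peaks the values had a Spearman correlation of 0.944 (bootstrap 95% interval 0.944 to 0.945), and peaks within a library are not independent replicates. With the longer list shortened to the length of the other by peak value, the shares were 76.9% for replicate 1 and 76.2% for replicate 2.

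**Figure D2:**
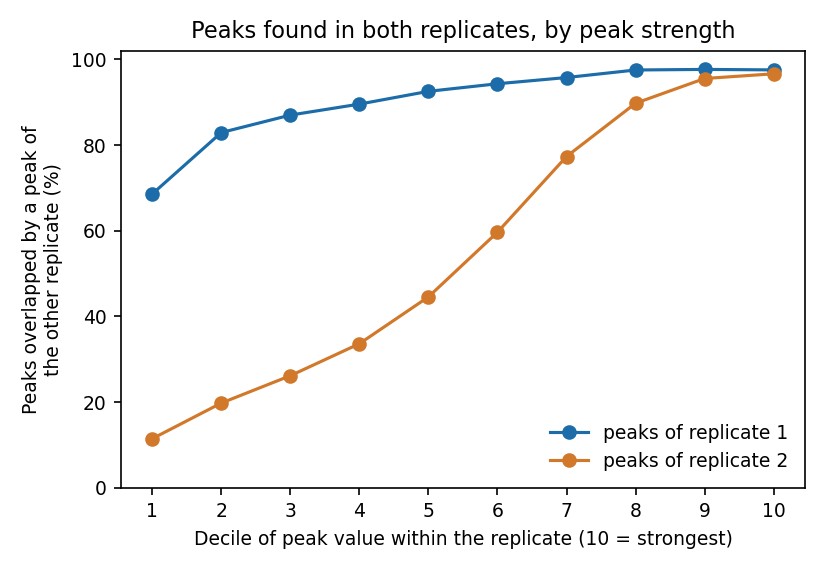
Percent of the peaks of each replicate that overlap a peak of the other (vertical axis) by decile of the authors' peak value within the replicate (horizontal axis, 10 being the strongest). The curve of replicate 2 rises from 11.5% to 96.6%, and that of replicate 1 from 68.6% to 97.5%.

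Promoters were the most over-represented part of the genome among the shared accessible sites, while introns and intergenic sequence held most of them by number. Regions within 1000 bp of the start of a protein-coding gene took 18.7% of the 117590 shared peaks (exact 95% interval 18.5 to 18.9) and 2.44% of the genome, a ratio of 7.66. Exons held 5.46%, introns 42.3% and intergenic sequence 33.5%, beside 4.18%, 40.01% and 53.4% of the genome. Taken separately, the replicates gave promoter shares of 17.2% ± 3.55 (SD, n = 2), exon shares of 5.70% ± 0.342, intron shares of 43.1% ± 2.06 and intergenic shares of 34.0% ± 1.14. The promoter share was 29.4% among regions found in replicate 1 alone and 9.54% among those found in replicate 2 alone. The former were 3586 regions, but only 59 genes had a promoter peak in replicate 1 and not in replicate 2. Most of these regions thus lay at promoters that had peaks in both replicates. Restricted to the stronger 50% of the shared peaks, the promoter share was 27.5%, and no test was made of these shares.

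Promoters of adipocyte genes were accessible more often than those of other genes, and promoters of genes of other lineages less often. Both replicates had a promoter peak at 12074 of 21829 protein-coding genes (55.3%), with 12133 genes in replicate 1 and 12996 in replicate 2, or 57.6% ± 2.80 (SD, n = 2). All 21 genes of fatty acid and triglyceride synthesis had one, as did all 20 housekeeping genes. So did 21 of 22 adipogenic transcription factors, 20 of 22 genes of lipid storage and lipolysis, 15 of 16 glucocorticoid response genes and 22 of 26 preadipocyte and fibroblast genes. These 6 lists were above the other genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 17 lists, with adjusted p from 4.38e-05 to 0.00527. The members without a promoter peak in both replicates were Mlxipl, a carbohydrate-sensing activator of lipogenic genes, Mgll, a lipase of monoglycerides, and Adrb3, a lipolytic receptor. Further ones were Tat, a liver aminotransferase, and 4 preadipocyte genes with Dlk1 and Wnt10b, an inhibitor of adipogenesis, listed foremost. Among adipokines and genes of the insulin response 16 of 21 had a promoter peak, with Lep and Rbp4 listed foremost of those without (Fisher's exact test, adjusted p = 0.0870). Matched on promoter CpG content and with a window of 2500 bp this list also stood above other genes (permutation and exact tests, adjusted p = 0.0233 and 0.0139, range over 7 alternatives 0.00576, from replicate 2 alone, to 0.189). Thermogenic genes of brown and beige fat had 7 of 17, with Ucp1 and Cidea, a lipid droplet protein of brown fat, among those without (Fisher's exact test, adjusted p = 0.329). Bone and cartilage genes had 6 of 18 (Fisher's exact test, adjusted p = 0.100), and the osteoblast regulator Sp7 and the bone matrix gene Bglap had no promoter peak. This list stood below other genes with a promoter window of 500 bp and in the stronger 50% of each replicate's peaks (Fisher's exact test, adjusted p = 0.000787 and 0.0244, range over 7 alternatives 0.000787 to 0.782). The preadipocyte list lost its call in the stronger 50% of each replicate's peaks and with a promoter window of 500 bp (Fisher's exact test, adjusted p = 0.0855 and 0.0509, range over 7 alternatives 0.000453 to 0.0855).

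Accessible promoters were less frequent in 8 lists. These were endothelial (1 of 16), pluripotency (3 of 15), epithelial (4 of 18), hepatocyte (5 of 20), skeletal muscle (5 of 20), blood and immune (5 of 19), neuronal (6 of 20) and olfactory receptor genes (34 of 1133). By Fisher's exact test the adjusted p was 0.000178 for endothelial, 0.0131 for pluripotency and for epithelial, 0.0159 for hepatocyte and for muscle, 0.0241 for blood and immune and 0.0307 for neuronal genes. The lineage regulators and markers without a promoter peak in both replicates included Pecam1 and Cdh5 of endothelium, Pou5f1 and Nanog of pluripotent cells, Cdh1 and Epcam of epithelium, Alb and Ttr of liver, Myod1 and Myog of muscle, Ptprc of blood, and Neurod1 and Neurog2 of neurons. Compared with genes of like promoter CpG content, the hepatocyte, muscle and blood lists no longer passed (permutation test, adjusted p = 0.482, 0.411 and 0.482). Over 7 alternatives the adjusted p of these exact or permutation tests began at 3.40e-05, 0.00136 and 0.00224 and ended at 0.482, 0.649 and 0.482. With a promoter window of 2500 bp, 3 lists stood below the other genes in place of 8 (endothelial, hepatocyte and olfactory receptor genes). Under hotspots in place of peaks the blood and neuronal lists did not pass (Fisher's exact test, adjusted p = 0.0503 and 0.0820, ranges over 7 alternatives 0.00224 to 0.482 and 0.00136 to 0.206). With the peaks of replicate 2 alone the blood and pluripotency lists did not pass (Fisher's exact test, adjusted p = 0.181 and 0.0749, ranges over 7 alternatives 0.00224 to 0.482 and 9.67e-05 to 0.0749).

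Distal accessible sites were concentrated around the genes of adipocyte function. Of the shared peaks 95618 (81.3%) lay more than 1000 bp from every protein-coding start site, and 78174 of these had such a site within 100 kb, with a median of 2 per gene. Adipogenic transcription factors had a mean of 15.5 distal shared peaks per gene (16.6 in replicate 1 and 29.95 in replicate 2). The ratio to genes with territories of like length was 2.81. It is 2 raised to the difference in mean log2(count + 1), not a ratio of mean counts, as are the other ratios of distal lists. Rxra, the partner receptor of Pparg, had 36, Zfp423, a regulator of preadipocyte commitment, had 34 and Cebpb, an early adipogenic factor, had 29. The Cebpb peak on chromosome 2 from 167691916 to 167692125, with values of 77 and 123, held the PPAR-RXR site AGGTCAAAGGTCA from 167692070 to 167692082. Genes of lipid storage and lipolysis had a mean of 9.41 (10.5 and 22.9 in the replicates) and a ratio of 2.73, with 43 at Lpl, the lipoprotein lipase, 16 at Mgll and 14 at the hormone-sensitive lipase gene Lipe. Adipokines and genes of the insulin response had a mean of 11.6 (13.1 and 23.7) and a ratio of 2.65. There were 41 at the insulin receptor substrate Irs2 and 24 at Nampt, an enzyme of NAD synthesis. Genes of fatty acid and triglyceride synthesis had a mean of 9.14 (10.1 and 20.6) and a ratio of 2.53, with 25 at the desaturase Scd1, 21 at Insig1, a regulator of sterol sensing, and 14 at Lpin1, a phosphatidate phosphatase. For each of these 4 lists the permutation test with 100000 draws gave a two-sided p of 2e-05, the smallest it can give, and an adjusted p of 5.67e-05. Matched also on promoter state, the ratio was 1.83 for adipogenic transcription factors, 1.89 for synthesis, 2.20 for lipid storage and 2.30 for adipokine genes. Endothelial and epithelial genes had 1.95 and 1.83 under that setting, so the first 2 of these lists did not stand out from them. With no matching the ratio was 4.35 for adipogenic transcription factors. With the peaks of replicate 2 alone, the ratio was 4.27 for lipid storage and lipolysis.

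Further lists also had more distal shared peaks than matched genes. Glucocorticoid response genes, whose hormone is part of the usual induction mix, had a ratio of 2.60 (permutation test, adjusted p = 5.67e-05). There were 20 at the receptor co-chaperone Fkbp5, 19 at the phosphatase Dusp1 and 16 at the zinc finger factor Zbtb16. Preadipocyte and fibroblast genes had a ratio of 2.00, with 27 at Twist2, 23 at the collagen gene Col1a2 and 19 at Col6a1 (permutation test, adjusted p = 9.71e-05). Epithelial genes had a ratio of 1.67, with 31 at Trp63, a regulator of stratified epithelium, and 8 each at Epcam and Krt8 (permutation test, adjusted p = 0.00620). Housekeeping genes had a ratio of 1.62, with 20 at Ywhaz and 13 at Actb (permutation test, adjusted p = 0.00246). In both of the last lists the difference was lost under alternatives. Epithelial genes had an adjusted p of 0.266 among the stronger 50% of shared peaks and 0.0539 with assignment within 20 kb (permutation tests, range over 9 alternatives 0.000291 to 0.266). Housekeeping genes had 0.0593 when matched also on promoter state and 0.293 with no matching (permutation tests, range over 9 alternatives 0.00178 to 0.293).

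The remaining lists did not pass the test of distal counts, apart from the olfactory receptor genes. Thermogenic genes had a ratio of 1.52, with 24 at Ppargc1b and 14 at Ppargc1a, both coactivators of mitochondrial genes, and 11 at the fatty acid receptor Ppara (permutation test, adjusted p = 0.0566). Bone and cartilage genes had a ratio of 1.49, with 17 at Sox5, 13 at Runx2 and 13 at Spp1 (permutation test, adjusted p = 0.0566). Each passed in 4 of 9 alternatives, both with the peaks of replicate 2 alone (permutation tests, adjusted p = 0.0354 and 0.0327), with genes matched also on promoter state (0.00598 and 0.00624) and with no matching (0.0130 and 0.0136). Thermogenic genes also passed with assignment within 50 kb (0.0367) and bone genes with replicate 1 alone (0.0489; permutation tests, ranges over 9 alternatives 0.00598 to 0.137 and 0.00624 to 0.410). Ratios were 1.34 for endothelial genes, with 13 at Flt1 and 11 at Pecam1, 1.19 for hepatocyte genes, with 12 at Apob, and 1.12 for muscle genes, with 9 at Mb. They were 1.02 for blood and immune genes, with 8 at Csf1r, 0.941 for neuronal genes, with 26 at Snap25, and 0.825 for pluripotency genes, with 9 at Dppa3. The permutation tests gave these 6 lists adjusted p from 0.223 to 0.905. Endothelial genes passed when promoter state was matched and with no matching (permutation tests, adjusted p = 0.00166 and 0.0411, range over 9 alternatives 0.00166 to 0.751). Pluripotency genes passed below matched genes among the stronger 50% of shared peaks (permutation test, adjusted p = 0.0408, range over 9 alternatives 0.0408 to 0.713). Olfactory receptor genes lay below matched genes, with a ratio of 0.552 (permutation test, adjusted p = 5.67e-05), which was 0.361 with no matching.

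**Figure D3:**
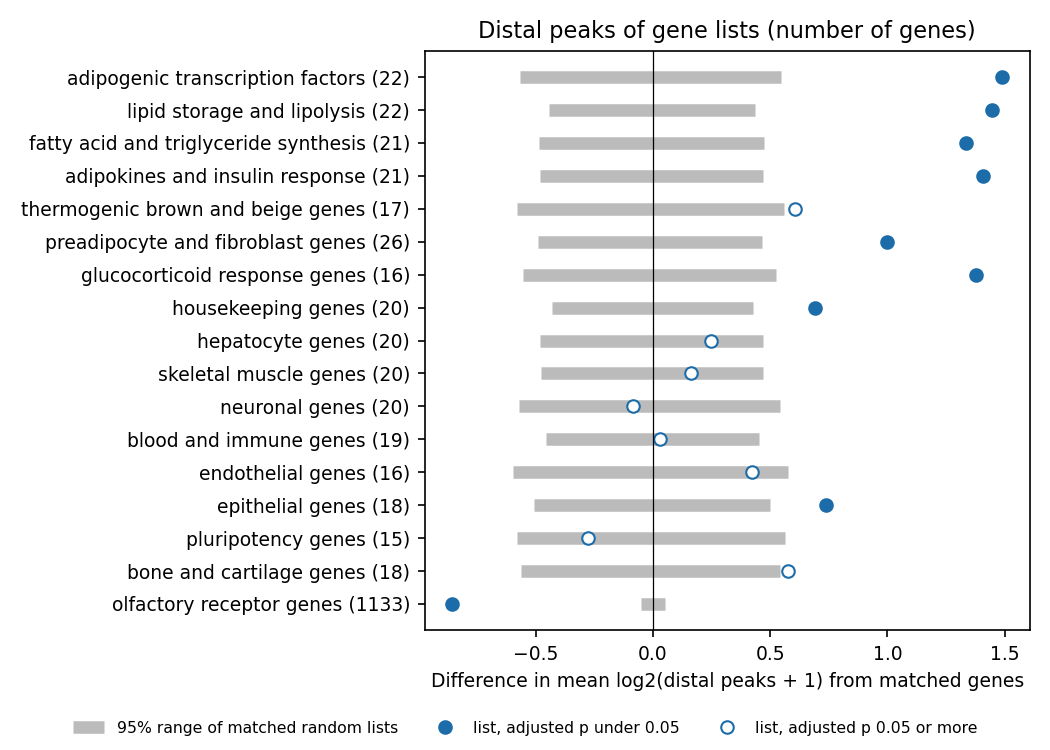
Difference between the mean log2(distal shared peaks + 1) of each gene list and that of genes matched on territory length (horizontal axis), with the number of genes in brackets, grey bars for the 95% range of matched random lists, filled points for adjusted p under 0.05 and open points otherwise. The 4 adipocyte function lists lie between 1.34 and 1.49, and olfactory receptor genes at -0.86.

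Distal accessible sites were enriched for binding motifs of the chromatin organiser CTCF and of several factors known from adipocytes. CTCF matches occurred in 5.75% of distal shared peaks and 0.0396% of flanking windows, a log2 ratio of 6.47 after subtraction of the median of shuffled motifs (6.39 in replicate 1 and 5.95 in replicate 2). NF1 full sites reached 3.20 (3.43 and 3.45), and C/EBP sites 2.06 (1.98 and 1.87), with matches in 1.86% of peaks and 0.407% of flanks. AP-1 sites, bound by Fos and Jun proteins, occurred in 7.81% of peaks and 2.42% of flanks and reached 1.71, EBF sites 1.28, glucocorticoid receptor sites 1.25 and STAT5 sites 1.00. MEF2 at 1.89, MyoD at 0.92, TEAD at 0.74 and ETS at 0.73 completed the 11 of 22 motifs that exceeded each of their 20 shuffled versions. The PPAR-RXR element, the direct repeat bound by Pparg and Rxra, was found in 0.305% of peaks and 0.106% of flanks, and its corrected log2 ratio of 0.85 ranked 5 of 21 among itself and its shuffles. REST at 1.99, PU.1 at 0.41, FOX at 0.37, NFY at 0.32, HNF1 at 0.15, RUNX at 0.09, NRF1 at -0.08, SOX at -0.19, GATA at -0.21 and OCT at -0.22 also lay within the range of their shuffles. The glucocorticoid receptor motif was within its shuffles among the stronger 50% of peaks (0.89), and ETS with flanks at 5000 bp (0.46), among replicate 2 peaks (0.37) and among the stronger peaks (1.03). FOX exceeded its shuffles among replicate 1 peaks (0.36) and with flanks at 5000 bp (0.42), and NFY among the stronger peaks (0.47).

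Promoter peaks were led by NRF1, ETS, REST and NFY, each at a lower ratio in distal peaks, with CTCF, ETS, MEF2 and C/EBP called in both. NRF1 at 4.42, ETS at 4.34, REST at 3.42, NFY at 2.94, CTCF at 2.83 and C/EBP at 1.09 each exceeded their 20 shuffles. MEF2 at 1.88 and OCT at 0.93 also did, although their matches were no more frequent in promoter peaks than in the flanks, at 0.259% and 0.278% for MEF2 and 0.619% and 0.796% for OCT. NRF1 and NFY bind the promoters of many widely expressed genes. AP-1 at 0.60, STAT5 at 0.79, TEAD at 0.23 and EBF at -0.56 lay within their shuffles there. Distal peaks had a GC content of 48.4% and their flanks 44.1%, while promoter peaks had 59.2% and their flanks 45.2%. The gap was thus wider at promoters. Column shuffles do not keep CpG pairs, so a difference in CpG content would remain in these ratios.

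**Figure D4:**
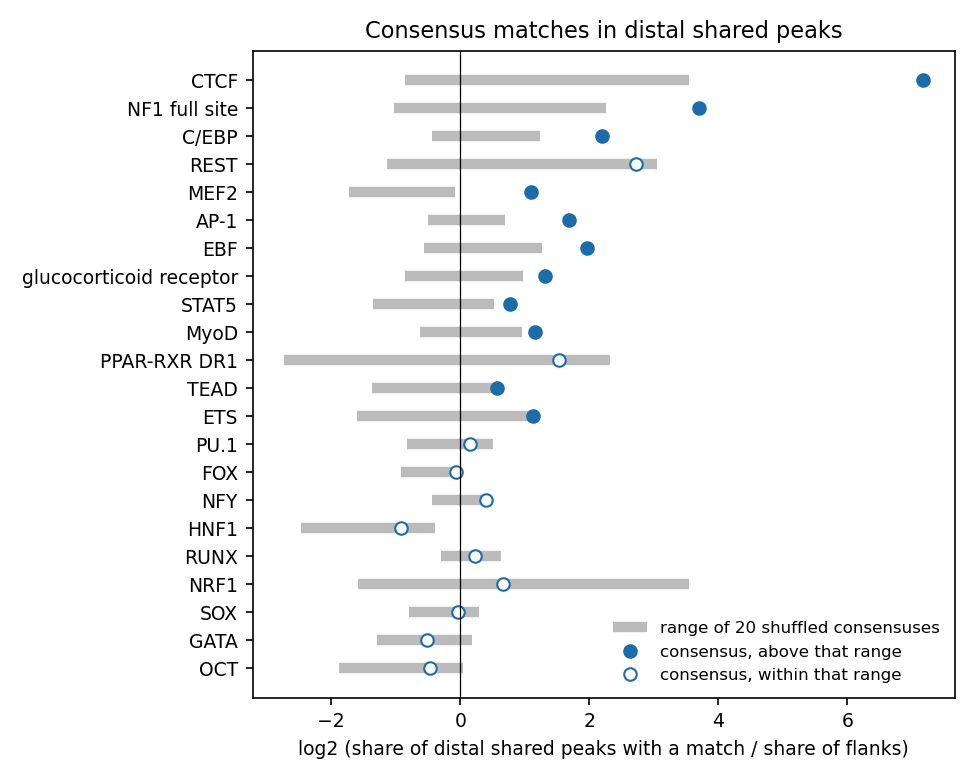
Log2 ratio of the share of distal shared peaks with a motif match to the share of flanking windows, before subtraction of the shuffles (horizontal axis), for 22 motifs, with grey bars for the range of 20 shuffled versions, filled points for motifs above it and open points for motifs within it. CTCF stands at 7.17 and C/EBP at 2.19, and the PPAR-RXR element at 1.53 lies within its bar.

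Runs of closely spaced accessible sites lay at adipocyte, glucocorticoid response and housekeeping genes more often than at other genes. Joining shared peaks less than 10 kb apart gave 48060 clusters, and the 500 with the most peaks, each with at least 12, had 968 genes at them, or 4.43% of all. Among glucocorticoid response genes 7 of 16 lay at such a cluster, among adipokines and genes of the insulin response 7 of 21, and among genes of lipid storage and lipolysis 7 of 22. The counts were 6 of 20 among housekeeping genes, 5 of 22 among adipogenic transcription factors and 4 of 21 among genes of fatty acid and triglyceride synthesis. The two-sided Fisher's exact test gave these lists adjusted p of 2.26e-05, 0.000126, 0.000133, 0.000577, 0.00674 and 0.0305 in that order. That test was not matched on territory. Its members were not all independent, as Mt1 and Mt2 lay at the same cluster and Lcn2 counted in the glucocorticoid and adipokine lists. Preadipocyte and fibroblast genes had 4 of 26 and blood and immune genes 3 of 19 (Fisher's exact test, adjusted p = 0.0561 and 0.0937). Of the 8 other lists tested apart from olfactory receptors, thermogenic, hepatocyte, muscle, neuronal, endothelial and epithelial genes had 1 each, and pluripotency and bone genes none (Fisher's exact test, adjusted p from 0.676 to 1.00). No olfactory receptor gene of 1133 did (Fisher's exact test, adjusted p = 3.07e-22). The synthesis list lost its call with 200 clusters, and the glucocorticoid list with joining at 20 kb (Fisher's exact test, adjusted p = 0.175 and 0.133, ranges over 7 alternatives 0.000355 to 0.175 and 3.70e-07 to 0.133). Preadipocyte genes passed with the peaks of replicate 1 alone and with 1000 clusters (Fisher's exact test, adjusted p = 0.0118 and 0.0327, range over 7 alternatives 0.0118 to 0.726).

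The cluster with the most peaks stood apart from the rest. It ran for 424 kb on chromosome 10 from 117376116 to 117799925, held 632 shared peaks, and covered the start sites of Cpsf6, a messenger RNA processing factor, Cpm, a carboxypeptidase, Mdm2, the inhibitor of p53, Slc35e3 and Nup107. Replicate 1 had 19.2 peaks per 10 kb there with a median value of 126, and replicate 2 had 20.4 with a median value of 148. The 50 kb on either side had 1.0 and 2.5 per 10 kb with median values of 37.5 and 40. Past that flank, the 10 kb from 117280001 to 117290000 again held 17 and 18 peaks, with median values of 123 and 148. They belonged to a cluster of 16 shared peaks at Lyz2, too few to be named a dense cluster. A cluster of 71 shared peaks beside Lin7a, also on chromosome 10, from 107205456 to 107256765, and a short one of 24 peaks beside Ifng from 118611036 to 118623185 had medians of 126 in replicate 1 and of 147.5 and 148 in replicate 2. Others of the 10 clusters with the most peaks lay at 1600014C10Rik on chromosome 7 (43 peaks), Mdh1 on chromosome 11 (42), at Ppt2, Prrt1, Fkbpl, Atf6b and Tnxb on chromosome 17 (41), and at the homeobox gene Meis2 on chromosome 2 (41). Fewer were found at Tppp3, Zdhhc1, Hsd11b2, Atp6v0d1 and Agrp on chromosome 8 (38), at histone genes on chromosome 13 (36) and at Bahcc1 on chromosome 11 (35). Of all genes, Cpm had the most distal shared peaks with 227, followed by Cpsf6 with 139, Mdm2 with 93, the splicing factor Cwc22 with 86. After these came the phosphodiesterase Pde4d with 85, Lin7a with 71, the zinc finger gene Zbtb20 with 69, Slc35e3 with 58, the forkhead gene Foxp1 with 55 and Arhgap26 with 53. This ranking was not matched on territory, which was 138.6 kb for Cpm and 1378 kb for Pde4d. The peaks of Cpm, Cpsf6, Mdm2, Cwc22, Lin7a and Slc35e3 included clusters of at least 20 shared peaks with at least 10 per 10 kb, of which there were 12. Ifng, a cytokine gene, was named after its values were seen.

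**Figure D5:**
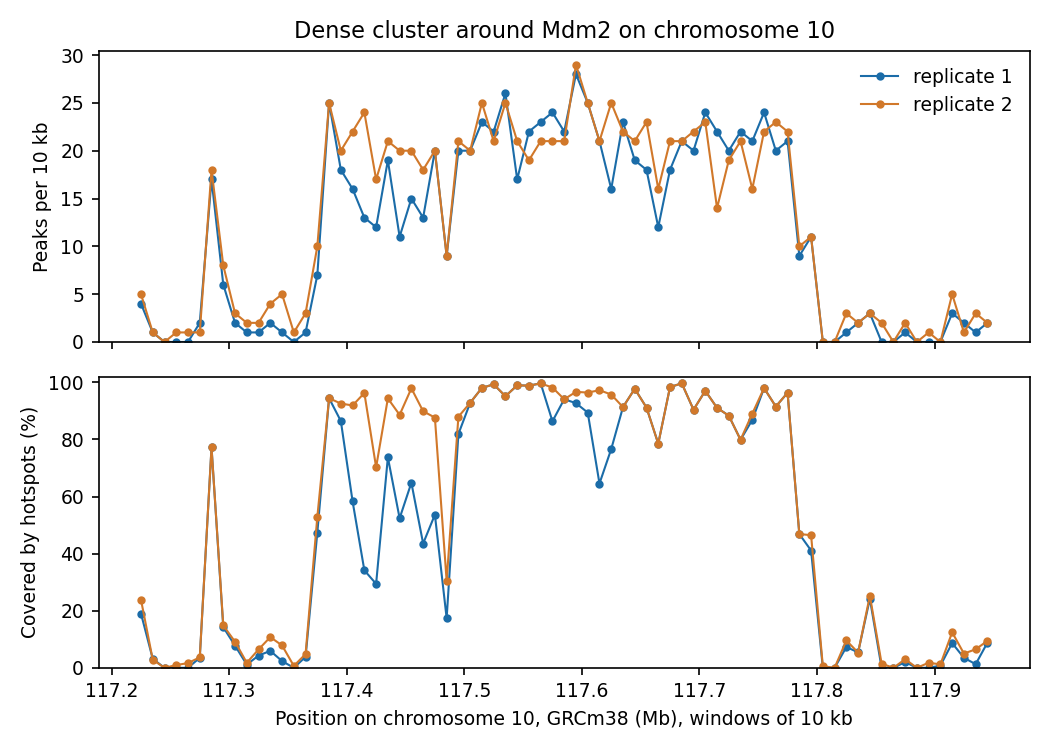
Peaks per 10 kb (upper panel) and percent of each 10 kb covered by hotspots (lower panel) along chromosome 10 in Mb (horizontal axis) around the cluster over Cpm and Mdm2, in replicate 1 (blue) and replicate 2 (orange). Inside the cluster the means are 19.2 and 20.4 peaks per 10 kb, with 79.7% and 89.5% covered, and both measures drop at its ends.

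Chromosomes differed in their density of accessible sites. The gene-rich chromosomes 11 and 19 were the densest, with 78.5 and 74.6 peaks per Mb in replicate 1 and 126 and 119 in replicate 2. The X chromosome had 22.5 and 38.3 peaks per Mb, 0.457 times the genome-wide density, and the Y chromosome held 17 and 75 peaks. Chromosome 10 had 59.8 and 93.6 per Mb, of which the dense clusters made up 12.1% and 8.26% of the peaks. Replicate 2 had 1.56 to 1.77 times the peaks of replicate 1 on every chromosome other than Y, where the ratio was 4.41.

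Sites found in 1 replicate alone were mostly weak. The 96366 peaks of replicate 2 without a partner had a median percentile of 27.0 within that list, and the 13033 of replicate 1 had 18.9. Of the latter 62.0% lay inside a hotspot of replicate 2, and of the former 5.73% lay inside a hotspot of replicate 1. Promoter peaks in replicate 1 alone were found at 59 genes and in replicate 2 alone at 922. All 17 list entries with a promoter peak in 1 replicate only had it in replicate 2, beginning with Lep, the phosphodiesterase Pde3b, the carbonic anhydrase Car3, the deiodinase Dio2 and the transcription factor Tbx1.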

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

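In this part, the dense clusters and all tests of them were chosen only after the clusters had been seen, and the other tests were planned or chosen before their results were known. Regions outside the assembled nuclear chromosomes, which entered no comparison, held peaks in both libraries. The mitochondrial genome had 17 peaks in replicate 1 and 17 in replicate 2, and unplaced and unlocalized scaffolds had 320 and 586. They are listed because they lie in data that no comparison used, and with no control library their number was not tested.

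Replicate 2 had 1.62 times the peaks of replicate 1. Against another set of strong regulatory elements open in replicate 2, 3.38% of its strongest 10% of peaks had no partner in replicate 1. Elements of moderate strength are not covered by that value, since 40.3% of the peaks in decile 6 and 22.7% in decile 7 had no partner. A difference in depth or calling sensitivity may account for the pattern, but the depth itself is unknown. The peaks found in replicate 2 alone had a median percentile of 27.0 within their list, which other causes could also give. In a comparison chosen later and without a test, CTCF matches were fewer in distal peaks of replicate 2 alone than in shared peaks of the same value (0.931% and 3.71%). Peak value alone does not account for that, while the ratios for AP-1 and TEAD were 0.954 and 0.999. The labels name different technical replicates for the libraries but no biological difference, so no other biological explanation was tested.

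Distal peaks were denser near the 4 lists of adipocyte function genes than near matched genes, with ratios from 2.53 to 2.81. With genes matched also on promoter state all 4 lists passed, at lower ratios of 1.83 to 2.30. Other lists passed as well, among them endothelial genes at 1.95 and epithelial genes at 1.83. Transcript levels were not measured, so this matching does not cover how active a promoter was. An accessible promoter alone would not account for all of the difference, since all 4 lists passed. Neither would weak calls near the threshold, since with the stronger 50% of shared peaks all 4 passed. A hypothesis left open is that these are regulatory elements of the adipocyte programme, which may be so for the 4 lists, although no undifferentiated library was analysed here. Distal means only more than 1000 bp from a start site, so peaks inside genes count. Exons held 6 of 14 shared peaks at Fabp4, 2 of 5 at Slc2a4 and 8 of 44 at Lpl, while Adipoq, Cebpa and Cd36 had none in exons. Accessibility along gene bodies was not tested apart from regulatory elements. Glucocorticoid response genes, at a ratio of 2.60, and preadipocyte and fibroblast genes, at 2.00, also passed, so the pattern was not confined to the 4 lists.

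On chromosome 10, 3 dense clusters held 727 shared peaks, and in the cluster of 424 kb around Mdm2 the median peak value was 126 in replicate 1 and 148, near the ceiling, in replicate 2. In these clusters 11.8% of distal peaks (exact 95% interval 9.56 to 14.5) had a match to any of the 11 motifs that exceeded their shuffles. The share was 26.2% in peaks of the same strength elsewhere and 9.35% in flanking windows. The ratio of 0.452 argues against a dense array of separate regulatory elements that use these motifs. Since the motifs were called on distal peaks nearly all outside dense clusters, elements with other motifs could not be seen. The interval treats neighbouring peaks as independent. Extra copies of these segments in the cells, with background cutting called as peaks, may explain the pattern, but dense clusters on other chromosomes had a like share of 13.5% beside 26.8% (ratio 0.503), some of them with ordinary peak values, so a low share is not particular to chromosome 10. Repeat sequence that draws reads from other places cannot be told apart from this, because 22.9% of the peak bases were masked as repeats beside 33.0% of the clusters as a whole, between the bounds set for the test. In the whole genome 36.4% was masked, so these clusters were not richer in masked repeats than the genome. No copy number was measured, since alignments were not used here.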

How the results depend on the processing

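The alternative without the dense clusters was chosen after seeing the data, and it changed no call of the distal lists, clusters or motifs and moved each position share by less than its spread. No paired analysis was possible because there was 1 group. For the main results, 114 values under alternatives kept their direction and side of the threshold or moved by less than their spread, and 26 moved. For single lists and motifs, 419 kept their call or their lack of one, 29 lost a call, 23 gained one and 4 changed sign with a call in at least 1 of the settings; sign changes with no call in either were not counted. The share of replicate 1 peaks with a partner was 85.0% with a reciprocal overlap of 50%, 96.2% for the top 50% of each list, 76.9% for lists of equal length and 95.6% for hotspots. For replicate 2 it was 52.4%, 59.9% and 76.2% under the first 3. Spearman's correlation was 0.875 over the top 50% of shared peaks and 0.587 over hotspots, whose values reach a ceiling. With promoter windows of 500 and 2500 bp, the promoter share was 13.5% and 25.4%, the exon share 6.42% and 4.55% and the intron share 45.6% and 38.1%, as the window itself sets, and the intergenic share was 31.9% at 2500 bp. Over the top 50% of shared peaks, promoters took 27.5%, introns 37.1% and intergenic sequence 30.2%. Leaving out each replicate gave 14.7% to 19.7% for promoters, 5.46% to 5.94% for exons, 41.7% to 44.6% for introns and 33.2% to 34.8% for intergenic sequence. Promoter lists below other genes numbered 3 at 2500 bp and 5 when matched on promoter CpG, and distal lists below matched genes 2 over the top 50% of shared peaks. Under promoter peaks in place of distal ones, EBF was at -0.56, MyoD at -0.034, NRF1 at 4.42 and OCT at 0.93, opposite in sign to the distal values. Except where the window or ceiling is named, the cause was not tested. Unknown depth limits what the absence of a peak shows in either replicate.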

Other observations

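The test in the second paragraph was planned before its result was seen, and the comparison of motifs in replicate 2 peaks was chosen after the peaks found in 1 replicate had been seen. Away from the dense clusters, the genes with the most distal shared peaks were Pde4d with 85, Zbtb20 with 69, Foxp1 with 55, Arhgap26 with 53, Arid5b, a regulator of adipogenesis and lipid metabolism, with 52, the Wnt effector Tcf7l2 with 52, Kalrn with 51, Tnr with 48, Tenm4 with 47 and Magi1 with 46. The last 6, and Zfp385b below, were named after their values were seen. These counts were not matched on territory. It was 1378 kb for Pde4d, 637 kb for Zbtb20, 648.8 kb for Foxp1 and 520.1 kb for Arhgap26, beside 169.4 kb for Pparg with 26 distal shared peaks. Distal peaks found in replicate 2 alone had fewer CTCF matches than shared peaks of the same value, with no test made. CTCF matches were present in 0.931% of the former and 3.71% of the latter, a ratio of 0.251, while C/EBP matches were at 1.35% and 1.57%, and the ratios of REST, MEF2, AP-1, TEAD and EBF were 0.451, 0.626, 0.954, 0.999 and 1.04. A further 3 dense clusters, on chromosome 2, lay beside Zfp385b and Cwc22. Their median values were 75.5, 92 and 84 in replicate 1 and 125, 134 and 131 in replicate 2.

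A hypothesis was that C/EBP or PPAR-RXR matches are more frequent in distal peaks near adipocyte genes than near other genes. Such a match was present in 23 of 982 distal peaks at the 4 adipocyte lists, or 2.34% (bootstrap 95% interval over genes 1.49 to 3.27), and in 2.08% at other genes, with a permutation p of 0.820, so the data neither show nor exclude a difference of that size. Taken apart, the ratio of the shares was 0.975 for C/EBP and 1.97 for PPAR-RXR, the latter from 6 peaks (permutation p = 0.711 and 0.179).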
